A study of Homo sapiens with 6 samples.

How the data were processed

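Total RNA of HD-MyZ cells, an established Hodgkin lymphoma line, was measured on 6 arrays with 2 colours each. Every array set RNA of cells carrying an inducible short hairpin RNA (shRNA) against CPEB1 against RNA of untreated cells with the same replicate number. There were 3 biological replicates per the series design text, and each was hybridised on 2 arrays, a direct one with the knock-down RNA in Cy5 and a dye swap with the knock-down RNA in Cy3. All 6 arrays form 1 group, and the comparison lies within each array.

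Per the labels, the authors extracted mean foreground and background intensities of both channels for each spot and corrected the foreground by the background. The scanner software, the normalization and their versions are not given in the sources used here. The deposited table holds 1 log ratio per spot and array, read here as log2 because its base is not stated. In a base 10 reading every value would be larger by one constant factor. Signs and tests against 0 would stay, and counts with a bound on size would change. Array medians lay between -0.01 and 0.01, so the authors' values were already centred. Of 45220 rows, 5233 had no value on any array and 34044 had a value on all 6 arrays. The authors' rule for leaving spots out is not given in the sources used here, and no intensities were used here, so no filter on dim spots by signal could be made.

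The direction of the deposited ratios is not stated. The plan made before the data were examined was to turn the swap arrays by the dyes in the labels. The check described in the results favoured swap arrays that already run the same way as the direct arrays, and their signs were therefore kept. The check does not settle the reading. The choice was made after seeing the data, and the counts with the swap arrays turned are given as an alternative. Ratios are given as knock-down over untreated cells, which is an assumption. The labels put the knock-down RNA in channel 1 on all 6 arrays, and ratios were taken as channel 1 over channel 2. The data hold no check of this direction. If it was the inverse, every sign below turns together.

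Rows are spots of a custom array with many spots per gene, laid out for splicing. Gene names came from the array's annotation, in which 40146 spots had 1 gene symbol and none had several. The remaining 1803 spots with a value had no name in it. Of 939 transcript accessions, 906 matched the RefSeq gene table of the GRCh38.p14 assembly, which was used for names only, and 61 of them received a current symbol; unmatched ones kept the array's symbol. Spot positions and sequences were not used here, so a spot is not assigned to an exon, junction or transcript end. The targeted gene, CPEB1, had 0 spots among the named ones, so its level could not check the labels or the direction.

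A spot was used in a replicate when both of its arrays had a value and was tested when at least 2 replicates did, which left 35667 spots, 34090 of them named. The direct and swap values of a replicate were averaged, which removes a dye effect that is equal in both orientations and leaves n = 3. A gene's value was the mean over its spots. Of 805 genes tested, 339 had 1 spot and 466 had several, with a median of 63 and at most 321. The 3 replicate values were tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3) and Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05. The same test was run per spot, on 0.5 of the difference between orientations (the dye effect), and on each spot minus the mean of the other spots of its gene, for genes with at least 3 spots.

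Before the data were examined, 29 gene lists were fixed. The 12 lists with at least 5 members measured in all replicates were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over lists. Named genes followed a rule fixed at the same time: the 12 largest changes in each direction among genes past the threshold with the same sign on all 6 arrays, up to 4 members per list by smallest p among those past the threshold, and up to 2 members as values where none passed. CPEB1 came first in that rule and could not be given. The rule named 68 genes; other genes named below were chosen after their values were seen.

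The tests were run on simulated data with the spread of the real replicates. Values were drawn independently, without dye effects or correlation between spots or genes, so the shares hold for that setting only. Unchanged were 602 of 802 genes (1.83% of them called), 24044 of 34044 spots (1.13%) and 22774 of 32209 spots set against their gene (1.32%). At a log2 change of 0.2, 81.2% of changed genes were recovered among 802 simulated genes, 75.6% of changed spots among 34044, and 76.3% of spots moved against their gene among 32209; at 0.1 the shares were 47.8%, 32.5% and 27.9%. The alternatives were the 6 arrays as separate values with and without a replicate block, each orientation alone, leaving out each replicate, other centring, scaling and quantile normalization, other variance models and thresholds, other spot filters and gene summaries. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.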

Results

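Log ratios of CPEB1 knock-down over untreated HD-MyZ cells were measured on 6 arrays, as 3 biological replicates with a direct and a dye-swapped array each. CPEB1 is an RNA-binding protein that recognises cytoplasmic polyadenylation elements in the untranslated ends of mRNAs and controls poly(A) tail length and translation. The arrays carried values for between 36612 and 37633 spots. The SD of the deposited log ratios over spots lay between 0.25 and 0.29.

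The first question was whether the deposited ratios of both dye orientations run the same way. Across spots, arrays of the same orientation correlated with r of 0.70 to 0.84, and direct arrays correlated with swap arrays with r of -0.39 to -0.03. The arrays of one replicate share their RNA, so the deviations of each array from the mean of its orientation were compared. Across 802 genes, these deviations correlated with r of 0.32, 0.56 and 0.41 within the 3 swap pairs. Across spots the correlations were lower, at 0.19 to 0.23. Genes accounted for 42.3% of the variance over spots of genes with several spots in the mean of the orientations as deposited, against 22.7% with the swap arrays turned. Genes and spots are not independent replicates. The difference between orientations repeated better between replicates than their mean did (r of 0.85 to 0.89 against 0.63 to 0.75 across spots). The turned reading would take that difference as the knock-down effect. The signs were kept as deposited on the basis of the deviations across genes, which remains an inference. Ratios are given as knock-down over untreated, the assumed direction, on a scale read as log2.

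The comparison of knock-down with untreated cells asks which mRNAs change level when CPEB1 is reduced. The largest increases were in CSAD, an enzyme of taurine synthesis (log2 ratio 0.96 ± 0.12, SD, n = 3), ACKR3, an atypical chemokine receptor (0.95 ± 0.07), JAG1, a Notch ligand (0.88 ± 0.05), and DLX2, a homeobox transcription factor (0.86 ± 0.04). The largest decreases were in HYAL1, a hyaluronidase (-0.88 ± 0.10), BIRC3, an inhibitor of apoptosis (-0.56 ± 0.03), CDC6, which loads the replicative helicase at origins (-0.52 ± 0.06), BTN2A1, a butyrophilin (-0.52 ± 0.07), and BCL2A1, an antiapoptotic BCL2 relative (-0.50 ± 0.02). Of 805 genes, 178 were higher and 94 lower in knock-down cells at an adjusted p under 0.05, and 177 of these 272 genes had the same sign on all 6 arrays. The median size over the called genes was 0.20, and 16 of them reached 1.5-fold on the scale read as log2. On a base 10 scale, 153 would reach it. The excess of increases lay mainly among genes with 1 spot, with 110 higher and 35 lower, against 68 and 59 among genes with several spots. The direct arrays alone gave 144 higher and 146 lower, and the 6 arrays with the swap arrays turned gave 232 higher and 300 lower.

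The other genes of the 12 largest increases were LTBP2, which binds the extracellular matrix (0.82 ± 0.12), CDC25B, a phosphatase that activates cyclin-dependent kinases (0.77 ± 0.18), the membrane transporter SLC67A1 (0.73 ± 0.09), the interferon-stimulated gene IFIT1 (0.71 ± 0.11), the neurotrophin receptor NGFR (0.64 ± 0.04), the tyrosine kinase FYN (0.64 ± 0.15), the cold-inducible RNA-binding protein CIRBP (0.64 ± 0.05) and PCDHGC3, whose spot stands for the protocadherin gamma cluster in the array's annotation (0.63 ± 0.09). Their adjusted p-values in limma lay between 0.0011 for NGFR and 0.00495 for FYN. The other large decreases were in ITGA5, a subunit of a fibronectin receptor (-0.43 ± 0.05), RNF7, a RING subunit of cullin ubiquitin ligases (-0.40 ± 0.06), the transcription factor E2F1 (-0.39 ± 0.10), CD274, which encodes the immune checkpoint ligand PD-L1 (-0.36 ± 0.02), the phosphatase PPM1G (-0.36 ± 0.14), LSM11, a protein of histone pre-mRNA processing (-0.34 ± 0.04), and CCNA2, cyclin A (-0.34 ± 0.04). Their adjusted p-values lay between 0.00205 for CD274 and 0.0155 for PPM1G. All 12 increases and 10 of the 12 decreases rested on 1 spot each; RNF7 had 45 spots, 39 of them below 0, and CCNA2 had 36, 34 of them below 0.

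**Figure D1:**
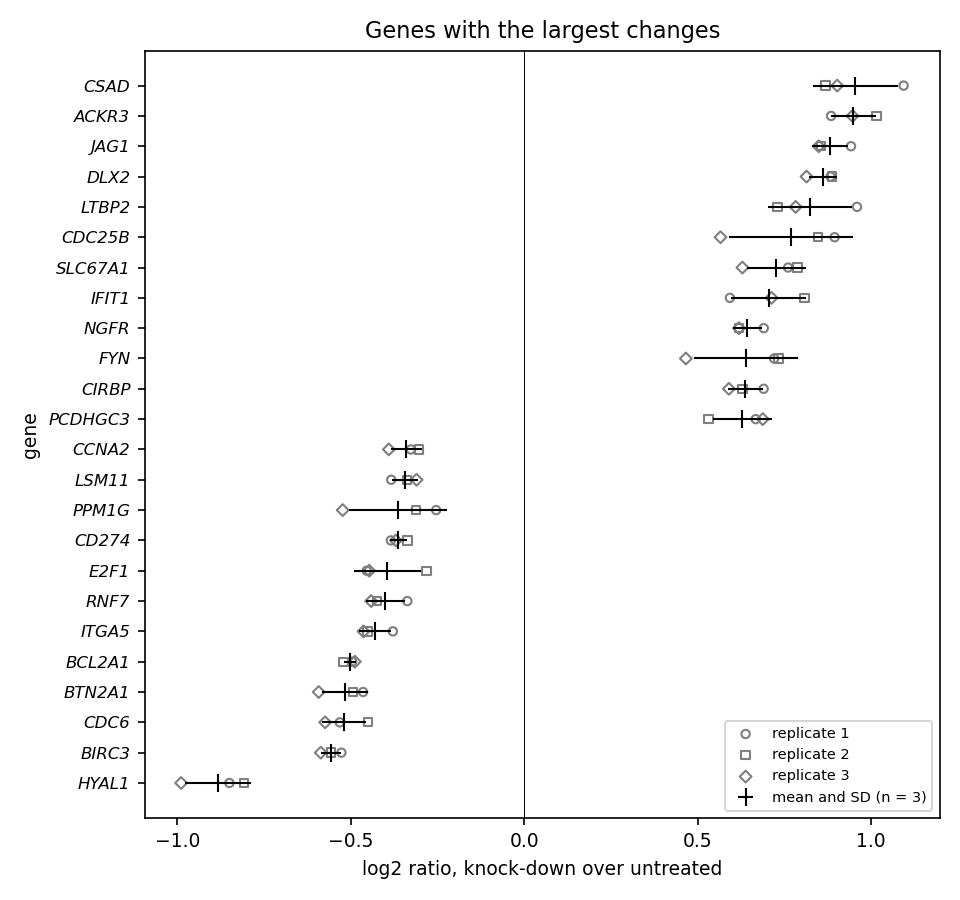
Log2 ratios of knock-down over untreated cells (horizontal axis) for the 12 largest increases and the 12 largest decreases (vertical axis), with the 3 replicate values as open symbols and the mean and SD as black bars. The means run from 0.96 for CSAD to 0.63 for PCDHGC3 among the increases and from -0.34 for CCNA2 to -0.88 for HYAL1 among the decreases, and all replicate values lie on the side of their mean.

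The count of called genes depended on the replicates and on the reading of the swap arrays: it was 124 without replicate 1, 104 without replicate 2 and 306 without replicate 3, and 532 with the swap arrays turned. With them turned, 181 genes were called under both readings, 73 of these with the same sign, so most of the 272 calls hold under the reading used here alone. The ranking of the 24 largest changes also rests on it: with the swap arrays turned, 5 of the 12 increases stayed above 0 and 11 of the 12 decreases below 0, and the largest size among the 24 was 0.42. CSAD then had -0.11, ACKR3 -0.24, JAG1 -0.27, BIRC3 -0.37 and CDC6 -0.42, and HYAL1 had 0.000152. The means on the direct and the swap arrays were -0.92 and -0.19 for BIRC3 and -0.94 and -0.09 for CDC6. With the signs as deposited, dye effects were large beside these changes. Of the 272 called genes, 51 had opposite signs in the means of the direct and the swap arrays.

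**Figure D2:**
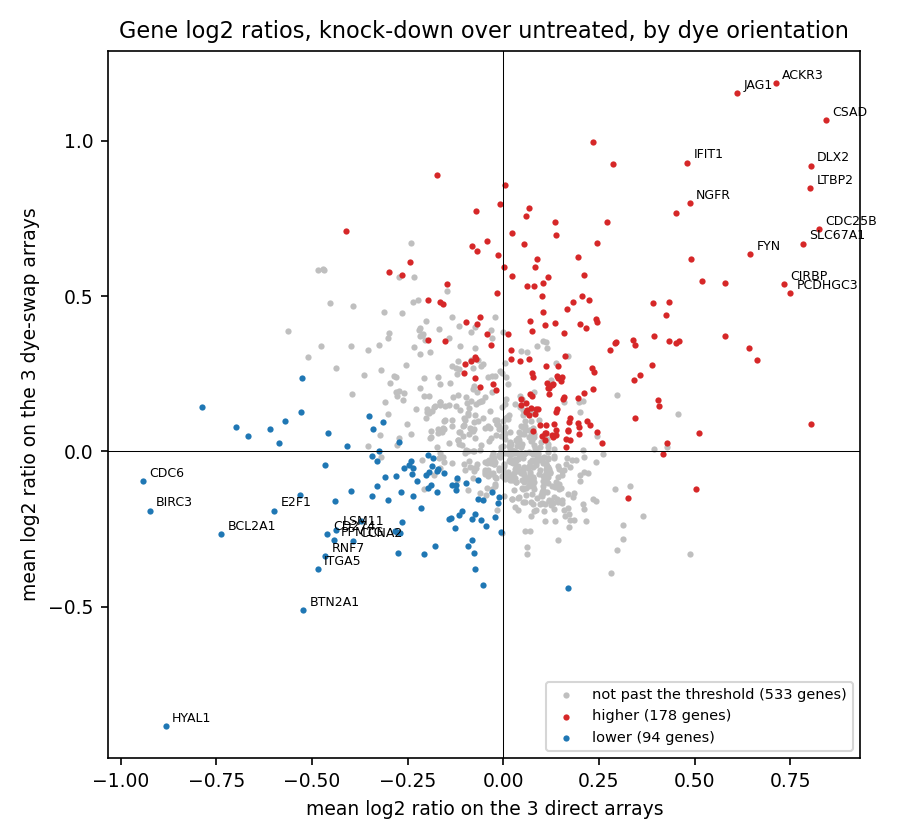
Mean log2 ratio of each gene on the 3 direct arrays (horizontal axis) and on the 3 dye-swap arrays (vertical axis), with genes past the threshold in red (178 higher) and blue (94 lower), the 533 others in grey, and the 24 genes of the largest changes named. Across genes the orientations correlated with r of 0.18, and the named genes lie in the upper right and lower left.

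Of 14 measured genes of mitosis and the G2/M transition, 9 were lower in knock-down cells, among them CCNA2 (-0.34 ± 0.04), CDK1, the mitotic kinase (-0.25 ± 0.06), BIRC5, survivin (-0.22 ± 0.03), and MKI67, a marker of cycling cells (-0.20 ± 0.01). CDC25B was the 1 member that was higher (0.77 ± 0.18), and 4 did not pass. The mean of CDK1 was -0.47 on the direct arrays and -0.04 on the swap arrays. All 49 spots of BIRC5 and 63 of the 68 spots of MKI67 were below 0. Of 7 genes of DNA replication and the G1/S transition, 4 were lower (CDC6, E2F1, the helicase subunit MCM5 at -0.30 ± 0.16, and CCND3, a D-type cyclin, at -0.12 ± 0.03), 3 did not pass and none was higher. Adjusted over the list alone, 1 gene of mitosis was higher and 9 were lower, and 1 gene of DNA replication was higher and 5 were lower. The mitosis list lay 0.14 below the other genes, with a difference of -0.14 (camera adjusted p = 6.30e-05), and the replication list had a difference of -0.23 (adjusted p = 0.0196). With an estimated correlation neither list passed (adjusted p = 0.484 for both), nor did either with the swap arrays turned. In that turned reading MCM5 had 0.03 and CCND3 0.10, while CDC6 had -0.42 and E2F1 -0.20. CCNA2 had -0.05, CDK1 -0.21, BIRC5 -0.11, MKI67 -0.11 and CDC25B 0.05. The replication list did not pass on the direct (adjusted p = 0.347) or the swap arrays (0.0614) alone.

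NF-kB activity is a hallmark of Hodgkin lymphoma cells. Of 12 measured NF-kB targets, 5 were lower, none was higher and 7 did not pass. The members that were lower were BIRC3 (-0.56 ± 0.03), BCL2A1 (-0.50 ± 0.02), the signalling adaptor TRAF1 (-0.26 ± 0.12), the inhibitor NFKBIA (-0.19 ± 0.03) and the subunit gene NFKB1 (-0.12 ± 0.02). The counts were the same adjusted over the list alone. The list had a mean of -0.15 and a median of -0.05, and BIRC3 and BCL2A1, its lowest named members, rested on 1 spot each. It differed from the other genes by -0.19 (camera adjusted p = 0.00257, and 0.484 with an estimated correlation). It did not pass on the direct arrays alone (adjusted p = 0.347) or with the swap arrays turned, where NFKBIA had 0.06, NFKB1 -0.01 and BCL2A1 -0.24. TRAF1 was the 1 member past the threshold among 5 measured Hodgkin and Reed-Sternberg cell markers; CD40, CD86, TNFRSF8 and IL13 had values between -0.03 and 0.05.

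Immediate early and MAPK feedback genes included 3 that were lower and none that was higher among 5 measured. These were FOSL1, an AP-1 subunit (-0.23 ± 0.05), MYC (-0.18 ± 0.01) and the phosphatase DUSP1 (-0.15 ± 0.02); FOS had -0.04 and JUNB 0.13, without passing. The counts were the same adjusted over the list alone. The list differed from the other genes by -0.14 (camera adjusted p = 0.0343; adjusted p = 0.484 with an estimated correlation). The call was also lost without replicate 3 (adjusted p = 0.0744), with genes of 1 and of several spots centred separately (0.0519) and on the direct arrays alone, where the difference was 0.00907. With the swap arrays turned the list did not pass, and FOSL1 had 0.15, MYC 0.10 and DUSP1 0.04. MYC had all 28 spots below 0 and was also the 1 lower gene among 5 measured Wnt targets, where none was higher (camera adjusted p = 0.768).

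All 3 measured interferon-stimulated genes were higher in knock-down cells: IFIT1 (0.71 ± 0.11), the transcription factor IRF9 (0.49 ± 0.12) and IFIT3 (0.41 ± 0.09). Each rested on 1 spot and had the same sign on all 6 arrays, and the 3 counts were the same adjusted over the list alone. Genes with 1 spot lay higher as a class (median 0.08); with the classes centred separately the values were 0.62, 0.40 and 0.32, and all 3 passed. With the swap arrays turned, IFIT1 had -0.22, IRF9 0.15 and IFIT3 -0.21. With 3 members the list was too short for a list test.

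Apoptosis regulators moved both ways. Of 24 measured, 5 were higher, 4 lower and 15 did not pass, with the same counts adjusted over the list alone. The BH3-only genes BBC3 (0.62 ± 0.09) and PMAIP1 (0.36 ± 0.02) were higher, and the survival genes BIRC3 and BCL2A1 were lower. PMAIP1 had a mean of -0.17 on the direct arrays and 0.89 on the swap arrays, and BBC3 0.24 and 1.00. With the swap arrays turned, BBC3 had -0.38, PMAIP1 -0.53 and the death receptor gene TNFRSF10B -0.01. As a list, apoptosis regulators did not stand apart from other genes (camera adjusted p = 0.706). Among 8 measured p53 targets, BBC3 and TNFRSF10B (0.16 ± 0.03) were higher, none was lower and 6 did not pass, with the same counts adjusted over the list alone. The p53 list had a mean of 0.08 and a median of -0.01 (camera adjusted p = 0.861).

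Genes with a reported CPEB1-regulated mRNA were measured for 9 members. VEGFA, an angiogenic growth factor, was higher (0.38 ± 0.03) with 42 of its 48 spots above 0. MYC, CDK1, AURKA, the kinase that phosphorylates CPEB proteins in oocytes (-0.20 ± 0.04), and the mitotic kinase PLK1 (-0.14) were lower, and 4 did not pass. Adjusted over the list alone, 2 were higher and 5 lower. The list did not pass against other genes (camera adjusted p = 0.138), while fry, which asks whether members move one way on balance, gave an adjusted p of 0.0159. The result of fry was not particular to this list. It does not compare a list with other genes, and 6 of the 12 lists tested passed with it. The mitosis, replication, immediate early and TGF-beta lists had the same adjusted p in fry. In the CPEB family and its binding partners, AURKA and the RNA-binding protein MSI2 (-0.18 ± 0.06) were lower among 4 measured members, with the same counts over the list alone; MSI1 (-0.01) and ELAVL1 (-0.06) did not pass. The mean of MSI2 was -0.34 on the direct arrays and -0.02 on the swap arrays. With the swap arrays turned, VEGFA had 0.01, MYC 0.10, AURKA 0.11, CDK1 -0.21 and MSI2 -0.16.

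Among 7 cleavage and polyadenylation factors, 3 were higher and 2 lower, and the counts were the same over the list alone. CPSF6 (0.20 ± 0.05), CPSF1 (0.14 ± 0.05) and PABPC1 (0.29) were higher, the cytoplasmic poly(A)-binding protein gene PABPC4 (-0.25 ± 0.02) and CPSF2 (-0.16 ± 0.03) were lower, and the list did not pass (camera adjusted p = 0.706). Its mean was 0.02 and its median -0.03. Of 42 splicing factors, 8 were higher, 3 lower and 31 did not pass; adjusted over the list alone, 5 were higher and 3 lower. Examples were RBM5 (0.18 ± 0.02) and SRSF6 (0.11 ± 0.02) among the higher and TIA1 (-0.23 ± 0.04) and HNRNPA2B1 (-0.12 ± 0.03) among the lower members (camera adjusted p = 0.583 for the list).

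TGF-beta and EMT genes had 1 higher and 2 lower members among 7: SMAD7, an inhibitor of TGF-beta signalling (0.61 ± 0.12), TGFBR2, a TGF-beta receptor (-0.27 ± 0.01), and ITGA5. Adjusted over the list alone, 1 was higher and 3 lower, and the list did not pass against other genes (camera adjusted p = 0.397). With the swap arrays turned, SMAD7 had -0.16, TGFBR2 -0.0031 and ITGA5 -0.05. In the JAK-STAT list, STAT3 (0.11 ± 0.01) and the kinase gene PIM1 (0.15 ± 0.04) were higher and MYC was lower among 6 members, with the same counts over the list alone (camera adjusted p = 0.706). Of 3 cholesterol synthesis genes, SREBF2 (0.15 ± 0.02) and PMVK (0.18 ± 0.05) passed as higher, and over the list alone 1 more passed as lower; both had negative means on the direct arrays, -0.27 and -0.24. In the fit of the 6 arrays with a replicate block neither passed (adjusted p = 0.159 and 0.109). With the swap arrays turned, SREBF2 had -0.42, PMVK -0.43, STAT3 -0.02, PIM1 0.09 and MYC 0.10.

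**Figure D3:**
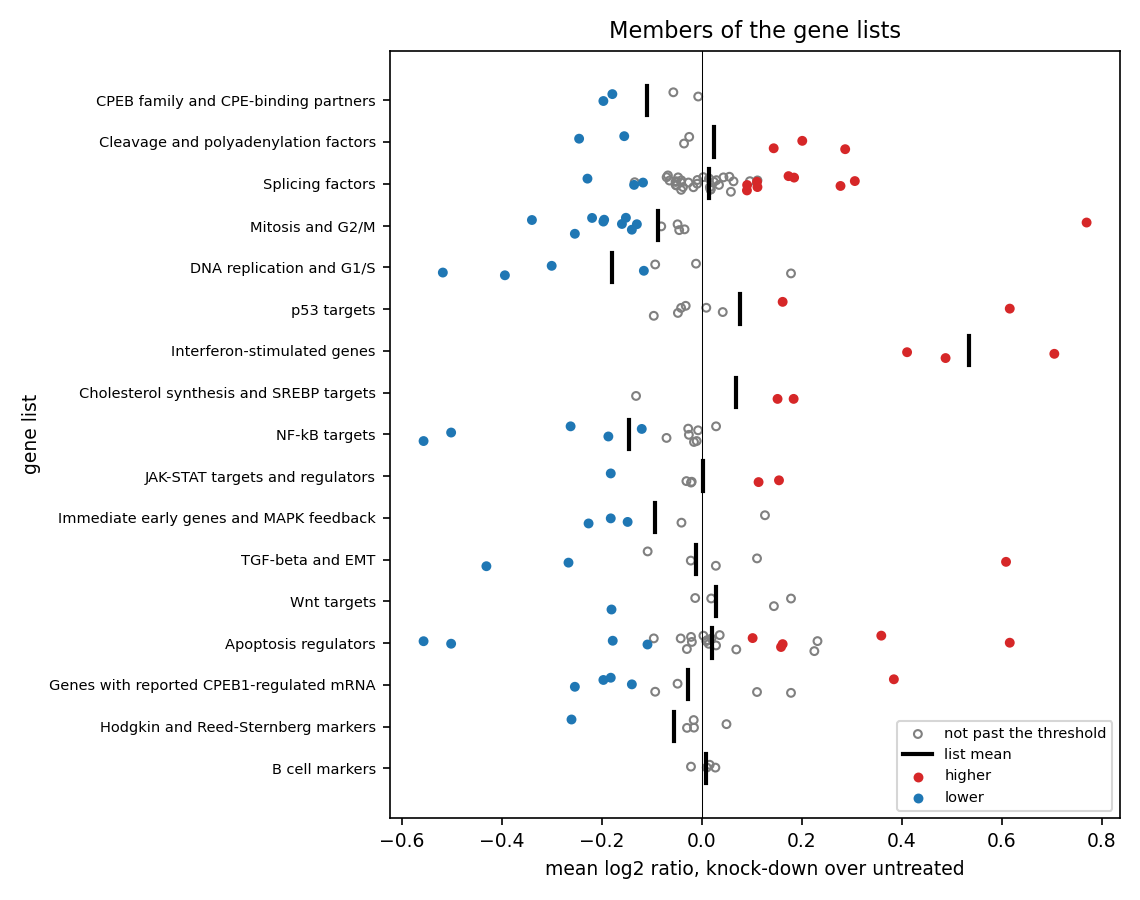
Mean log2 ratios of knock-down over untreated cells (horizontal axis) for the measured members of each gene list with at least 3 members (vertical axis). Filled points passed the threshold (red higher, blue lower), open points did not, and black bars mark list means; the interferon-stimulated genes lie between 0.41 and 0.71, and the called NF-kB targets between -0.56 and -0.12.

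Markers of other cell types gave few changes. None of 4 measured B cell markers passed; PAX5 had -0.02 ± 0.04 and CR2 0.03 ± 0.03. CD14 (-0.02 ± 0.08), FAP (-0.03 ± 0.02) and CDH1 (-0.02 ± 0.03), the single measured members of the monocyte, fibroblast and epithelial lists, did not pass. PAX5, CR2, FAP and CDH1 had opposite signs in the orientations. PAX5 had 0.16 on the direct and -0.21 on the swap arrays, and CDH1 had 0.18 and -0.22. With the swap arrays turned, PAX5 had 0.18, CDH1 0.20, CR2 0.09, FAP 0.07 and CD14 -0.0013. Without intensities, a gene that is not expressed cannot be told from an unchanged one. KDR, a VEGF receptor, was higher (0.14 ± 0.03) as 1 of 2 measured endothelial markers. In the lists with few members, HSPA8 passed as lower among 2 heat shock genes (-0.13 ± 0.04), with a mean of 0.17 on the direct arrays and -0.44 on the swap arrays and an adjusted p of 0.109 in the fit with the replicate block, and over the list alone both passed, 1 in each direction. The unfolded protein response genes TRIB3 (0.07 ± 0.04) and HSPA5 (0.11 ± 0.08) did not pass over all genes, and both passed over the list alone. CYCS, the 1 oxidative phosphorylation gene, had 0.23 ± 0.37, and VEGFA was the 1 gene of the hypoxia list. ACTB, the 1 housekeeping gene, had 0.20 ± 0.06 and passed as higher, with a mean of 0.42 on the direct arrays and -0.01 on the swap arrays. Histone, ribosomal protein and T and NK cell genes had no measured member.

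The comparison of single spots asks whether parts of a gene changed apart from the rest, as happens when the share of a transcript form changes. AIFM2, a flavoprotein oxidoreductase, had 6 of 56 spots between -1.14 and -0.85 while its median spot was at 0.05. MAP3K4, a stress kinase, had 4 of 109 spots between -1.12 and -0.65 with a median spot of -0.02. NUDT21, a subunit of the cleavage factor that selects poly(A) sites, had 4 of 39 spots between 0.54 and 0.56 and a median spot of -0.19. RNF7 had 4 spots between 0.51 and 0.57 in a gene whose median spot was at -0.48, and 4 of 69 spots of the splicing factor listed as SFRS7 lay between 0.54 and 0.58 with a median spot of -0.06; they were the highest of a group of spots that reached down to 0.43. SFRS7 is the old symbol of SRSF7, under which a further spot of the same gene, for another transcript, stood at 0.31. Across 466 genes with at least 3 spots, 3984 of 33751 spots differed from the other spots of their gene at an adjusted p under 0.05 in limma, 2143 above and 1841 below. A difference of at least 0.5 was reached by 93 of them, 60 above and 33 below, in 49 genes. Extreme spots draw the mean of the others, so the count of 3984 and its split can also hold spots in the bulk of their gene. In AIFM2, 24 of 56 spots differed, 6 of them by at least 0.5, and in NUDT21 32 of 39 differed. With the swap arrays turned, 17210 spots differed from the other spots of their gene, and more lay below than above.

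**Figure D4:**
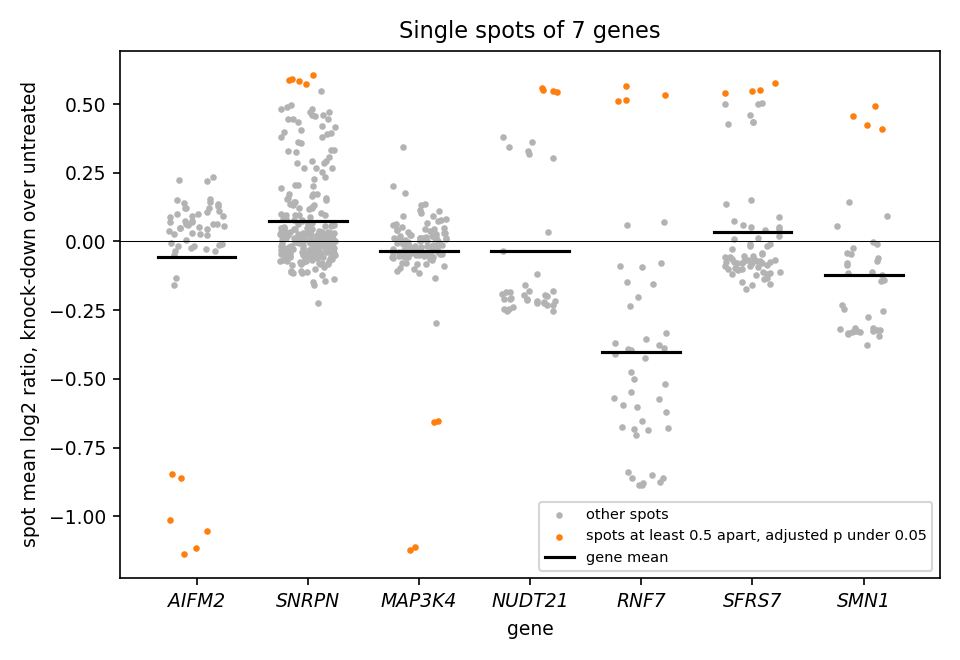
Mean log2 ratio of knock-down over untreated cells (vertical axis) for every tested spot of the 7 genes with the most spots at least 0.5 from the rest (horizontal axis); orange points are those spots and black lines are gene means. In AIFM2 the 6 orange spots lie between -1.14 and -0.85, far from the other spots of the gene, and in NUDT21 the 4 orange spots lie above 0.5 while most others lie below 0.

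These genes were chosen after their values were seen, as those with the most such spots. The others were SNRPN, with 5 such spots of 253 between 0.57 and 0.61, and SMN1, with 4 of 39 between 0.41 and 0.49. SMN1 has a near-identical copy, SMN2. The SNRPN spots were the highest of a series, with the next at 0.55 and 0.50, and NUDT21 held further spots between 0.30 and 0.38. The 6 spots of AIFM2 deviated by -1.10 to -0.80, with an adjusted p between 0.00022 and 0.00111 in limma (n = 3). With the swap arrays turned, 4 of the 93 spots stayed at least 0.5 from the rest of their gene, and the median size of their deviations fell from 0.62 to 0.18. The number of deviating spots was 1878 without replicate 1 and 1507 without replicate 2.

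Taken spot by spot, 7312 of 35667 spots passed the threshold, 4115 higher and 3197 lower. In called genes with at least 3 spots, a median of 87.9% of the spots lay on the side of the gene's mean; in 55 of those 127 genes over 90% did, BIRC5 and MYC among them with all of their spots. VEGFA and TIA1 held spots on both sides, from -0.60 to 0.77 and from -0.65 to 0.27. The count of called spots was 4543 without replicate 1 and 3917 without replicate 2.

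With the signs as deposited, the dye effect is 0.5 of the difference between the orientations. It passed the threshold for 18347 of 35667 spots, and its SD over spots was 0.19, against 0.15 for the knock-down ratio. Genes such as PMAIP1, SREBF2, HSPA8 and ACTB carried dye effects larger than their mean ratios. The dye effect repeated between replicates with r of 0.85 to 0.89 across spots, and the knock-down ratio with r of 0.63 to 0.75. With the swap arrays turned, the quantity named dye effect here would be the knock-down effect, and these values do not exclude that reading.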

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

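The tests of the orientation of the arrays, of dye bias for the interferon genes and of single faulty spots were chosen after the results were seen; the others were set before. Of 70 measures tested for an array far from the other 5, 2 stood out, and chance alone marks about 1 in 20. CPSF1 had 0.29 on the direct array of replicate 1 against 0.07 to 0.15 on the others. The SD of the log ratios over spots was 0.286 on the direct array of replicate 3 against 0.254 to 0.263 on the others. Outside the comparisons of named genes, 297 spots without a gene name passed the threshold, 167 higher and 130 lower, with log2 ratios from -0.66 to 0.78.

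The direct and swap arrays resembled each other little, and the sign of a result can depend on how they are joined. Had the swap arrays been deposited with the sign of the dyes, the arrays of one replicate would deviate in opposite directions; their deviations correlated above 0 in all 3 replicates, at 0.318 or more across genes. A dye bias of the spots could account for the low resemblance: 0.5 of the difference between orientations repeated between replicates with r of 0.854 or more. A dye bias specific to a replicate could also make its arrays deviate together, and with the swap arrays turned the repeated difference would be the knock-down effect. Both readings stayed open, since 0 arrays without a biological difference were in the design.

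The 3 interferon-stimulated genes IFIT1, IFIT3 and IRF9 were higher in every replicate, on 1 spot each. Genes with 1 spot lay higher as a class; with the classes centred separately the lowest of the 3 was IFIT3 at 0.32. With the signs as deposited, the values argue against dye bias: the lowest mean of either orientation in any of the 3 genes was 0.20. With the swap arrays turned, the same values would be dye bias, so this stayed open with the reading of the swap arrays. Expression of any shRNA, or the treatment of the cells, could raise interferon-stimulated genes apart from CPEB1: 0 arrays with another shRNA were in the design, so this and an effect of CPEB1 cannot be told apart. The same limit holds for the genes of cell division and the NF-kB targets.

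The 93 spots at least 0.5 from the other spots of their gene, in genes such as AIFM2, MAP3K4 and RNF7, were found in both directions. For the 63.4% that had another spot of their gene within 0.05, a single faulty spot is a less likely source. The share was 8.60% for a gene drawn at random. Spots above 0.6 lay in 41 genes and spots below -0.6 in 18, so a low share for a random gene was likely in advance. For the rest of the 93 spots, single faults stayed open. Genes with such spots had no larger share of missing values than other genes (difference in medians -0.0138, 95% bootstrap interval -0.0452 to 0.0193). That share belongs to whole genes and does not measure the signal of the 93 spots, so it cannot decide on weak signal. With the signs as deposited, a dye effect that is equal in both orientations cancels in their mean; with the swap arrays turned, 4 of the 93 spots stayed at least 0.5 from the rest, so such an effect stayed open with the reading of the swap arrays. An unequal one stayed open as well: 90 of the 93 spots deviated with the same sign in both orientations, and 89.2% by at least 0.5 of their mean deviation in each, just short of the 90% set before. Whether these spots mark transcript forms whose share changed stayed open as well. Cross-hybridisation was not tested, as spot sequences were not used here.

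Each sign pattern of the 3 replicate values was tested in place of the real one. Since 4 patterns exist, the share cannot fall below 0.05. In each case 1 pattern, the real one, gave as many calls, and the highest of the others gave 0: this held for the 272 genes, the 7312 spots, the 3984 spots apart from their gene and the 18347 spots with a dye effect.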

How the results depend on the processing

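Tests against a minimum size, on gene classes and with the classes centred separately were chosen after seeing the data. Turning the swap arrays by the dyes was the plan; keeping the deposited signs, and so giving the turned reading as an alternative, was chosen after seeing the data. The count of 272 genes stayed within 1.5 times under both fits with a replicate block (339, and 316 with a dye term as well), the direct arrays alone, median centring, common scaling, quantile normalization, robust eBayes, the spot filters and the median over spots. It was 166 with the 6 arrays as independent values, 553 with the swap arrays alone, 39 without moderation and 16 with 1.5-fold as well. It was 124 at an adjusted p under 0.01, 109 against a size of 0.1, 7312 per spot and 532 with the swap arrays turned. Refitted alone, genes with 1 spot gave 113 higher and 31 lower, against 110 and 35 in the main fit. Genes with several spots gave 113 higher and 101 lower alone, against 68 and 59 in the main fit. Leaving out a replicate gave 104 to 306. With the classes centred separately the split was 155 higher and 139 lower, against 178 and 94. The direct arrays alone gave 144 higher and 146 lower, and 33 of the 272 called genes had the other sign there. Of the 272 genes, 250 were also called in the fit with the replicate block. That fit averages the same arrays, so the signs had to be shared and it is no independent check. It estimated a correlation within replicates of -0.64, and of 0.40 with a dye term. A negative correlation lowers the standard error of a mean. The fit with the replicate block ended the calls of HSPA8, PMVK and SREBF2 and added HSPA5 and TRIB3 among the named genes.

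Called spots numbered 13151 on direct arrays, 17940 on swap arrays, 18347 with the swap arrays turned and 3917 to 8132 without a replicate. Spots apart from their gene numbered 11117, 14976 and 17210 in the same order, 1507 to 4801 without a replicate, and 93 with a difference of at least 0.5. The dye effect was called for 7312 spots with the swap arrays turned, and 13123 to 17015 without a replicate. Of the 4 gene lists called, 0 passed with an estimated correlation or with the swap arrays turned and 1 on direct arrays, while fry called 6. The replication list (adjusted p = 0.347) and the NF-kB list (0.347) lost their calls on direct arrays, and the replication list on swap arrays (0.0614).

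With the swap arrays turned, 39 of the 68 named genes kept their sign. On the direct arrays alone, the sign reversed for HSPA8 (0.17), SREBF2 (-0.27), PMVK (-0.24), PMAIP1 (-0.17), PAX5 (0.16), FAP (0.0329) and CDH1 (0.18), and for the differences of the cleavage (0.0491), JAK-STAT (0.0784), immediate early (0.00907) and TGF-beta (0.019) lists from other genes. On the swap arrays alone it reversed for TRIB3 (-0.0202), CR2 (-0.0673) and ACTB (-0.0081). With the classes centred separately it reversed for CR2 (-0.0608) and the cleavage list (0.0026). Leaving out a replicate gave -0.0606 to 0.020 for CD14, -0.0543 to 0.00712 for the Wnt list and -0.0601 to 0.0108 for the apoptosis list. The cause was not tested. Without replicate 1, 19 named genes lost their call, without replicate 2, 23, and without replicate 3, 1; fits on 2 replicates have fewer values. The main test is itself paired, since each ratio sets knock-down against untreated RNA of the same replicate. The level of CPEB1 had no alternatives, since no spot was named for it. Without intensities, signal over background could not be judged.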

Other observations

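The genes and lists here were chosen after their values were seen. RBM3, a cold-inducible RNA-binding protein gene, was higher in knock-down cells (0.51). Single genes that passed as higher included the kinase genes WEE1 (0.48) and PLK2 (0.46) and the transcription factor gene FOXO3 (0.40). So did 3 of 6 measured CDK inhibitors, CDKN1C (0.31), CDKN2D (0.21) and CDKN1B (0.19), with none lower, and the CDK inhibitors did not stand apart as a list (camera adjusted p = 0.581). CDKN1B had 0.50 on the direct and -0.12 on the swap arrays. SKP2 and MYBL2, which are linked to cell cycle progression, were lower (both -0.27). Of 19 cyclins and cyclin-dependent kinases, 4 were higher and 6 lower. The glucocorticoid receptor gene NR3C1 (0.61) and the initiation factor genes EIF2S2 (0.56) and EIF2S3 (0.31) were higher.

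In the SMN complex, which assembles splicing snRNPs, 3 of 8 measured genes were lower: GEMIN4 (-0.34), SMN2 (-0.20) and SMN1 (-0.12), while DDX20 was higher (0.17). SMN1 and SMN2 are near-identical copies, so their values are uncertain as separate genes. Of 14 SR proteins, 5 were higher and none lower, among them SRSF1 (0.17) and SRSF7 (0.31, on 1 spot). The other 69 spots of SRSF7, under its old symbol SFRS7, had a mean of 0.03. hnRNP genes had 2 higher and 4 lower of 22, Sm and LSm genes 2 and 2 of 15, U2 and SF3 genes 1 and 1 of 19, tri-snRNP genes 2 and 2 of 17, exon junction and export genes 1 and 2 of 16, neuronal RNA-binding proteins 1 and 1 of 14, and CLK and SRPK kinases 1 and 1 of 9. The MAP kinase cascade had 3 higher and 1 lower of 35, and TNF receptor signalling 5 higher and 1 lower of 25. None of these 13 lists stood apart from other genes at an adjusted p under 0.05 with camera.

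Spot pairs far below the rest of their gene were found in BCR (-1.32 and -1.24), SLC26A3 (-1.24 and -1.16), MAPK13 (-1.15 and -1.13) and PXN (-1.05 and -1.04), with gene means between -0.07 and -0.02. The BCR pair deviated by -1.33 and -1.25 on the direct arrays and by -1.33 and -1.26 on the swap arrays. CASP1 had 3 spots between 0.78 and 0.95 with a gene mean of 0.13.

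Genes with 1 spot had a median log2 ratio of 0.08, and 110 of them passed as higher and 35 as lower; genes with several spots had a median of 0.0003, with 68 higher and 59 lower. The difference in medians was 0.0837 (95% bootstrap interval 0.0643 to 0.109), being -0.0452 on the direct and 0.216 on the swap arrays.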
